A study of Mus musculus with 4 samples.

How the data were processed

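RNA-seq gene counts were analysed from 4 libraries of sorted cells of the mouse cortex at embryonic day 15.5. The groups were NPCs, sorted by Nestin-GFP fluorescence alone, and neurons, sorted by Nestin-GFP and DCX-mRFP fluorescence together, with 2 libraries each. Per the labels' protocols, cortices were dissociated by trituration, total RNA was extracted with TRIzol, and libraries followed an Illumina TruSeq protocol. The group of each library was taken from its title.

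The authors deposited 1 table of 23240 rows with an estimated count for each gene and library. The deposited counts were not scaled between libraries. Of 88416 values below 10000, all 88416 were multiples of 1 read of 101 bases within 0.01 base, so the deposited values appear to be bases covered divided by the read length. Per the submitters' processing notes, CASAVA 1.9, TopHat 1.2.0 and SAMtools 0.1.18 were used and the genome build was mm9, with no roles given. The counting tool, the gene annotation, the use of strand and the treatment of reads with several alignments are not given in the sources used here. Overlapping genes, antisense genes and near-identical copies are therefore uncertain. In 20 sets of rows with different names (43 rows), the counts of every library lay within 2 of each other at a mean of at least 100. One such set was Hba-a1 and Hba-a2, so reads shared by copies appear to have been counted for each. No coordinates are given, because the table holds none. The table held 25 names that look like calendar dates, which were kept as they stand, 11 names on more than 1 row (27 rows), which were treated as separate rows, and 0 mitochondrially encoded genes.

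The estimated counts were rounded to whole numbers. Genes with low counts were removed with filterByExpr, which left 15292 genes and removed 7948 rows, 4565 of them at 0 in every library. Libraries were scaled with TMM factors of 1.08, 1.07, 0.928 and 0.933. Neurons were compared with NPCs by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided and unpaired, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 change was the change divided by the square root of F. The fit had 2 residual degrees of freedom per gene and a prior of 13.9, and the biological coefficient of variation was 4.89%. The 33.3% that chance gives for groups that do not overlap is the share for 2 libraries against 2.

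Depth was close to equal between groups, at 52611828 to 55615142 counts per library. Duplicates were compared with the sampling noise of whole reads. Chi-square per gene was 4.56 for the NPC pair and 14.1 for the neuron pair, and 2.20 and 2.06 for genes with summed counts from 20 to 200. Duplicates thus differed by more than sampling noise and were kept as separate samples. A value near 2 at low counts is also what counting both ends of a fragment gives.

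Before the data were examined, 37 gene lists with 717 entries were written for cell types, pathways and complexes that the tissue could hold. Of their 705 genes, 701 were found in the table, 14 of them under another symbol, and 686 were tested. The others were not analysed here. Lists with at least 3 tested genes were compared with the other genes by camera in limma 3.58.1 with a preset correlation of 0.01. They were tested again with an estimated correlation, with fry, which asks whether a list's genes move one way on balance without comparing them to other genes, and with camera on ranks. Counts of members were adjusted over all genes tested and over the list alone.

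Genes to be named were set by rules before the data were examined. These were the reporter genes Nes and Dcx, 10 splicing regulators with Flna and Nin, the 8 genes with the highest and the 8 with the lowest log2 change among genes past the threshold with a mean of at least 20 CPM and groups that do not overlap, and, for each list, the 2 members with the smallest p and the 1 member with the highest mean CPM. Together these were 121 genes, and not all of them are printed. Members named as exceptions within a list (such as Ptprz1, Mbnl2, Homer2, Grik1 and those said to be picked out) were chosen after their values were seen, as were 13 gene families defined by their symbols.

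The test was checked on simulated counts for 15073 genes, for the comparison of neurons with NPCs. The means were those of the NPC libraries and the library sizes those of all 4 libraries. Only 200 genes were changed, far fewer than were called in the real data. It recovered 28 of 50 genes changed 1.25-fold (56%), 47 of 50 changed 1.5-fold, 50 of 50 changed 2-fold and 50 of 50 changed 4-fold. Of 181 calls, 6 (3.31%) were of unchanged genes. Of 37 unchanged lists, 0 were called by camera, and a list of 20 genes raised 1.5-fold had an adjusted p of 0.0346 with an estimated correlation. Genes were drawn independently of each other, so these list results do not check the preset correlation of 0.01.

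Alternatives planned before the data were examined were other scalings (RLE, upper quartile, library size only), DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 5 CPM in 2 libraries, leaving out the 50 genes with the most counts, the duplicate number as a block, leaving out each library in turn, and the other list tests. Tests against a minimum change with glmTreat, counts divided by 2, and a comparison without genes at least 8-fold higher in NPCs were added after the data were seen. Gene lengths for the additional observations came from NCBI RefSeq on GRCm38 and from GENCODE transcripts of that build, matched by symbol or synonym. Figures were drawn with matplotlib 3.10.9. The reporter transgenes and exon use were not analysed here.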

Results

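Gene counts were compared between neural progenitor cells (NPCs) and young neurons of the mouse cortex at embryonic day 15.5. Embryos carried a Nestin-GFP reporter, which marks progenitors, and a DCX-mRFP reporter, which marks newly formed neurons. Cells with green fluorescence only were sorted as NPCs, and cells with both colours were sorted as neurons. Each group held 2 duplicate RNA-seq libraries of total RNA. The NPC libraries held 53533953 and 55615142 counts, and the neuron libraries held 52611828 and 55329294 counts. Between 17036 and 17561 rows of the table had a count in a library. The gene with the most counts in every library was the tubulin gene Tuba1a, at 0.719% and 0.709% of counts in NPCs and 2.24% and 2.37% in neurons. Across genes, which are not independent replicates, Pearson's r of log values was 0.998 within each pair of duplicates and 0.936 to 0.938 between groups. The labels call the libraries duplicates and do not say whether they came from separate litters. The p-values therefore measure only the spread between these libraries, which may be technical.

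The series concerns differences in alternative splicing between progenitors and neurons. The table analysed here gives 1 value per gene, so the comparison is of gene expression, including that of the genes that regulate splicing. Exon use was not analysed here. Expression is given as mean CPM (counts scaled to a common library total) ± SD with n = 2 libraries per group, and log2 changes are neurons over NPCs ± standard error. All adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

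The genes behind the reporters served as a check of the labels and are no finding, because they defined the sort. Nes, which encodes the intermediate filament nestin, was at 100 ± 3.50 CPM in NPCs and 34.7 ± 2.40 CPM in neurons. Dcx, which encodes the microtubule-binding protein doublecortin, was at 480 ± 17.4 CPM in NPCs and 1399.8 ± 58.7 CPM in neurons. The NPC level of Dcx was 34.3% of the neuron level.

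The comparison of neurons with NPCs asks how expression differs between cells sorted as progenitors and cells sorted as neurons. Among genes with a mean of at least 20 CPM, the largest rises in neurons included those of the dynein intermediate chain gene Dync1i1, the neurofilament gene Nefl, Fam19a2, Sla, the splicing regulator Rbfox1, Bend6 and the synaptic scaffold gene Dlg2. Dync1i1 went from 24.9 ± 0.36 to 297 ± 20.5 CPM, a log2 change of 3.57 ± 0.07, and Dlg2 had a log2 change of 3.18 ± 0.11. The largest falls were those of genes known from oligodendrocyte precursors and blood vessels. Olig1 went from 43.9 ± 0.88 to 0.564 ± 0.161 CPM, a log2 change of -6.27 ± 0.13, and Pdgfra had a log2 change of -5.92 ± 0.10. Cldn5, Vtn, Kdr, Cd93, Cd34 and Nid1 followed, with log2 changes from -5.37 for the endothelial tight junction gene Cldn5 to -4.79 for the basement membrane gene Nid1.

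Of 15292 genes tested, 11108 (72.6%) passed an adjusted p of 0.05, 5467 higher in neurons and 5641 higher in NPCs. At an unadjusted p under 0.05 the count was 11379. With a change of at least 2-fold as well, 4578 genes passed, 1751 higher in neurons and 2827 higher in NPCs, which became 2599, 1099 and 1500 with a filter of 5 CPM. At 8-fold or more there were 66 genes higher in neurons and 582 higher in NPCs. Of the genes called, 2096 were higher in one group by under 25%. Both libraries of one group lay above both of the other for 13148 genes (86.0%), where chance gives 33.3%. The median SE of a log2 change was 0.08. The split between directions depended on the scaling. Genes higher in neurons were 49.2% of those called with TMM factors, and 33.5% (3840 against 7610 genes) with library size as the only scaling, which moved the median log2 change of all tested genes from -0.02 to -0.23. When the test asked for a change of more than 1.5-fold, 5387 genes passed.

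Gene lists fixed before the data were examined were compared with the other genes by camera. Of 37 lists, 24 passed an adjusted p of 0.05, 10 toward neurons and 14 toward NPCs. With the correlation between genes estimated from the 2 residual degrees of freedom, 0 lists passed, the smallest adjusted p was 0.0915, and 15 lists had an unadjusted p under 0.05. In 33 of the 37 lists, the counts of members adjusted over the list alone equalled those adjusted over all genes tested. The other counts adjusted over the list alone are given with their lists.

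**Figure D1:**
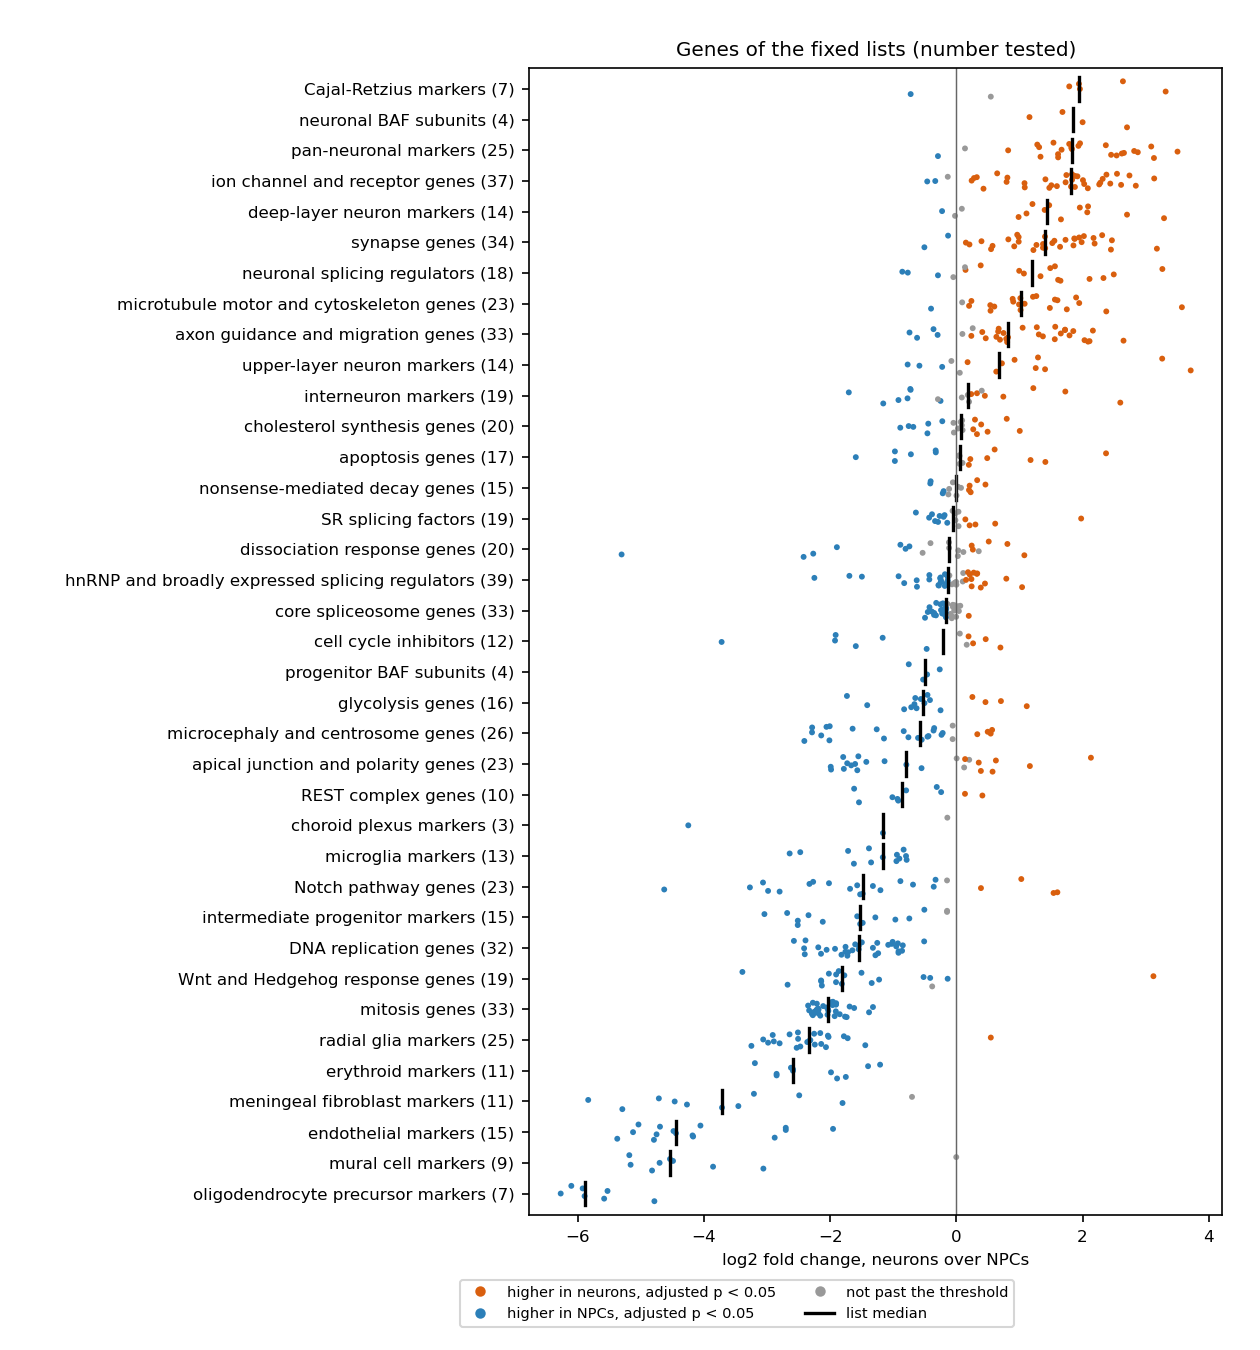
Log2 fold change of each tested gene (points, neurons over NPCs) in the 37 fixed lists, with the list medians as black bars and the number of genes tested in parentheses. List medians run from -5.89 for oligodendrocyte precursor markers to 1.94 for Cajal-Retzius markers, and those of apoptosis, cholesterol synthesis, nonsense-mediated decay and interneuron genes lie near 0 and turn negative with library size as the only scaling.

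Radial glia markers fell in neurons. Of 25 tested, 24 were higher in NPCs, with a median log2 change of -2.33 (camera adjusted p = 8.8e-43, and adjusted p = 0.0915 with an estimated correlation). Ednrb, an endothelin receptor gene, went from 154 ± 7.02 to 16.2 ± 0.595 CPM, Mfge8 had a log2 change of -2.89 ± 0.06, and the intermediate filament gene Vim had one of -2.51 ± 0.07. The exception was the receptor phosphatase gene Ptprz1, higher in neurons with a log2 change of 0.55. Markers of intermediate progenitors, the dividing cells between radial glia and neurons, were also higher in NPCs for 13 of 15 genes (median -1.52, camera adjusted p = 2.4e-12, and adjusted p = 0.107 with an estimated correlation). The proneural factor gene Neurog2 went from 1362 ± 10.1 to 212.6 CPM, and Btg2, an inhibitor of proliferation, had a log2 change of -2.51 ± 0.06. Pan-neuronal markers rose in neurons for 23 of 25 genes, with a median of 1.83 (camera adjusted p = 8.2e-36, and adjusted p = 0.0915 with an estimated correlation). Stmn2, a regulator of microtubules in growing axons, went from 99.5 ± 1.21 to 846 CPM, Myt1l had a log2 change of 2.88 ± 0.06 and Tubb3 one of 1.96 ± 0.06. Elavl4 was the 1 pan-neuronal marker higher in NPCs (-0.29 ± 0.05), and Rbfox3 did not pass. In the same libraries, endothelial markers were higher in NPCs with a median of -4.44 and oligodendrocyte precursor markers with a median of -5.89.

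Genes of the dividing cell were higher in NPCs. All 33 mitosis genes tested were higher in NPCs, with a median of -2.03 (camera adjusted p = 7.5e-42, and adjusted p = 0.107 with an estimated correlation). Mki67, a marker of cycling cells, went from 438 to 86.0 CPM, and the spindle gene Tpx2 and topoisomerase gene Top2a had log2 changes of -2.27 ± 0.06 and -1.90 ± 0.06. All 32 DNA replication genes were also higher in NPCs, with a median of -1.55 (camera adjusted p = 2.3e-21, and adjusted p = 0.107 with an estimated correlation). The helicase gene Mcm3 had a log2 change of -2.41 ± 0.06, Uhrf1 one of -2.57 ± 0.07 and the ribonucleotide reductase gene Rrm1 one of -1.25 ± 0.06. Of 26 genes of microcephaly and the centrosome, 20 were higher in NPCs and 4 in neurons, with a median of -0.58 (camera adjusted p = 1.2e-05, and adjusted p = 0.107 with an estimated correlation). Nde1 and Tacc3, which act at spindles and centrosomes, had log2 changes of -2.29 ± 0.06 and -2.06 ± 0.06, and Ckap5 one of -0.23 ± 0.06. The Ckap5 call was lost without NPC replicate 2, at an adjusted p of 0.091. Those higher in neurons included Kif2a, Pafah1b1 and Ndel1, picked out after their values were seen. Inhibitors of the cell cycle went both ways, with 4 of 12 higher in neurons (Cdkn2d, Cdkn1c, Cables1 and Rb1; 5 adjusted over the list alone), 6 higher in NPCs and a camera adjusted p of 0.23 (0.0013 with fry). Rbl1 and Cdkn2c had log2 changes of -1.91 ± 0.07 and -1.92 ± 0.10, and Btg1 one of -0.47 ± 0.05. Endothelial markers were higher in these NPC libraries too (median -4.44).

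Signalling genes of the progenitor niche were mostly higher in NPCs. In the Notch pathway, which keeps progenitors from differentiating, 18 of 23 genes were higher in NPCs and 4 in neurons (median -1.48, camera adjusted p = 9.7e-08, and adjusted p = 0.107 with an estimated correlation). The Notch target Hes5 went from 133 ± 6.45 to 16.8 CPM, the receptor gene Notch1 had a log2 change of -2.33 ± 0.06, and the pathway's transcription factor gene Rbpj one of -0.33 ± 0.06. The 4 genes higher in neurons were Dner, Dtx1, Rfng and Jag2, picked out after their values were seen. Of 19 Wnt and Hedgehog response genes, 17 were higher in NPCs (median -1.81, camera adjusted p = 3.3e-06, and adjusted p = 0.107 with an estimated correlation). The Wnt receptor gene Fzd8 had a log2 change of -2.67 ± 0.06 and the secreted Wnt antagonist gene Sfrp1 one of -1.77 ± 0.05. Rspo3, which encodes a secreted enhancer of Wnt signals, went the other way, from 9.73 ± 0.66 to 84.8 CPM. Genes of apical junctions and polarity were higher in NPCs for 13 of 23 and in neurons for 7, with a median of -0.79 (camera adjusted p = 0.014, and adjusted p = 0.26 with an estimated correlation). The cadherin gene Fat1 had a log2 change of -1.99 ± 0.07, Magi1 one of -1.73 ± 0.06 and the beta-catenin gene Ctnnb1 one of -0.55 ± 0.05. The call of this list was lost with limma-voom (adjusted p = 0.084) and with camera on ranks (adjusted p = 0.095). Some Notch genes are also known from blood vessels, and endothelial markers were higher in NPCs with a median of -4.44.

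Neuronal splicing regulators rose in neurons as a list, but not in every member. Of 18 tested, 13 were higher in neurons, 3 were higher in NPCs and 2 did not pass (median fold 2.30, camera adjusted p = 6.5e-08, and adjusted p = 0.107 with an estimated correlation). Rbfox1 went from 24.9 ± 0.65 to 239 CPM, a log2 change of 3.27 ± 0.06. Rbfox2, of the same family of RNA-binding proteins, went from 100 ± 2.83 to 281 CPM, a log2 change of 1.49 ± 0.06. Rbfox3 had a log2 change of 0.14 ± 0.07 that did not pass (adjusted p = 0.071). Without neuron replicate 1 it passed, at 0.22 with an adjusted p of 0.0012, and it was at -0.07 with library size only. Khdrbs2 and Elavl3 rose, with log2 changes of 2.50 ± 0.06 and 1.33 ± 0.05. Srrm4, a regulator of neuronal microexons, had a log2 change of 0.39 ± 0.06, from 86.2 to 113 CPM. Nova2 and Nova1, paralogous RNA-binding proteins, moved in opposite directions, with log2 changes of 1.00 ± 0.08 and -0.86 ± 0.10. Elavl4 was higher in NPCs (-0.29 ± 0.05), as was Mbnl2 (-0.77), picked out after its value was seen. Elavl2 was at 722 CPM in NPCs and 699 CPM in neurons and did not pass (-0.05 ± 0.05), though it passed with upper-quartile factors (-0.15) and library size only (-0.25).

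Ptbp1, a repressor of neuronal exons, fell from 161 ± 1.66 CPM in NPCs to 56.9 CPM in neurons, a log2 change of -1.50 ± 0.06 (edgeR adjusted p = 7.1e-13). Its paralog Ptbp2 was at 482 ± 7.42 CPM in NPCs and 533 CPM in neurons, a log2 change of 0.15 ± 0.05 (edgeR adjusted p = 0.021). The Ptbp2 call was lost without NPC replicate 1 (0.13) or NPC replicate 2 (0.16), with upper-quartile factors (0.045) and with the filter of 5 CPM (0.11), and its sign turned to -0.06 with library size as the only scaling. Flna and Nin, genes of the actin cytoskeleton and the centrosome that were named in advance, moved in opposite directions. Flna fell from 217 ± 6.46 to 92.9 CPM, a log2 change of -1.22 ± 0.05, and Nin rose from 56.1 ± 4.33 to 175 CPM, a log2 change of 1.64 ± 0.06.

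**Figure D2:**
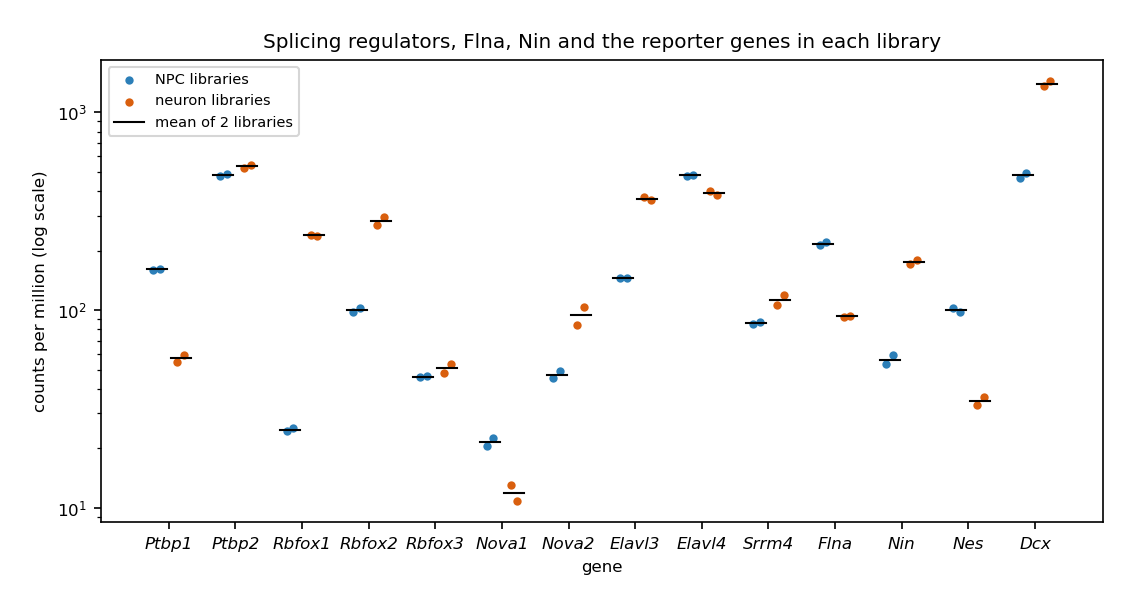
CPM (log axis) of splicing regulators, Flna, Nin and the reporter genes in each of the 4 libraries (points), with the mean of each group of 2 libraries as a bar. Ptbp1 lies at 161 CPM in NPCs and 56.9 CPM in neurons, and Rbfox1 at 24.9 and 239 CPM; Ptbp2 and Rbfox3, whose directions turn with library size as the only scaling, lie close together in both groups.

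Genes of the broadly used splicing machinery were tested as separate lists, and their difference from the neuronal regulators was not tested. Of 39 hnRNP genes and other widely expressed regulators, 12 were higher in neurons and 20 in NPCs, with a median of -0.13 (camera adjusted p = 0.37, and adjusted p = 0.0089 with fry). Qk, which encodes the RNA-binding protein quaking, had a log2 change of -1.69 ± 0.06, and Hnrnpk was at 2321 and 2491 CPM with a change of 0.10 ± 0.06 that did not pass. Without neuron replicate 2, Hnrnpk passed at 0.19, and it was at -0.11 with library size only. Of 19 SR proteins and their kinases, 5 were higher in neurons and 9 in NPCs, with a median of -0.06 and a mean of 0.02, which differ in sign (camera adjusted p = 0.999). Srsf12 rose with a log2 change of 1.98 ± 0.08 and the kinase gene Srpk2 with one of 0.62 ± 0.05, and Srsf1 fell with one of -0.34 ± 0.06. Of 33 core spliceosome genes, 1 (Prpf19) was higher in neurons and 20 in NPCs, with a median of -0.17 (camera adjusted p = 0.29). This list passed with limma-voom (adjusted p = 0.014), no low-count filter (0.023), fry (0.0079) and camera on ranks (0.018). Sf3a3 and Snrpb had log2 changes of -0.39 ± 0.05 and -0.42 ± 0.06. Sf3b1, at 0.04 ± 0.05, did not pass, and with library size only it passed at -0.17 as higher in NPCs (adjusted p = 0.0094). Of 15 genes of nonsense-mediated decay, the pathway that removes many misspliced transcripts, 5 were higher in neurons and 4 in NPCs (camera adjusted p = 0.999). These counts depended on the scaling. With library size only, those higher in neurons and in NPCs became 5 and 25 for the hnRNP list and 2 and 14 for SR proteins. They became 0 and 31 for the core spliceosome and 1 and 9 for nonsense-mediated decay. Upf1 and Upf3a both had log2 changes of -0.41, and Eif4a3 was at -0.13 ± 0.06 with an edgeR adjusted p of 0.053. Eif4a3 passed under 7 alternatives, with changes from -0.33 to -0.13. Splicing genes higher in NPCs, such as Ptbp1 and Qk, moved the same way as oligodendrocyte precursor (median -5.89) and endothelial markers (-4.44) in these libraries.

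Genes of synapses, excitability and axons were higher in neurons. Of 34 synapse genes, 32 were higher in neurons (median 1.41, camera adjusted p = 9.1e-17, and adjusted p = 0.22 with an estimated correlation). The vesicle genes Syt4 and Rab3a had log2 changes of 2.31 ± 0.06 and 2.19 ± 0.06. Homer2 and Syt11 were the members higher in NPCs, and the small change of Syt11 (-0.13 ± 0.05) was lost without either NPC replicate and with the replicate block. Of 37 ion channel and receptor genes, 34 were higher in neurons and 2, Grik1 and Grik2, in NPCs (median 1.82, camera adjusted p = 1.2e-18, and adjusted p = 0.107 with an estimated correlation). The glutamate receptor gene Gria2 went from 239 ± 2.98 to 1161 CPM. Of 33 genes of axon guidance and migration, 27 were higher in neurons (28 adjusted over the list alone) and 4 in NPCs (Epha4, Lrp8, Ntng1 and Sema6a; median 0.82, camera adjusted p = 1.7e-13, and adjusted p = 0.165 with an estimated correlation). The adhesion genes Cntn2 and Chl1 had log2 changes of 2.65 ± 0.06 and 2.11 ± 0.05, and the semaphorin receptor gene Plxna2 one of 0.66 ± 0.06. Of 23 microtubule motor and cytoskeleton genes, 21 were higher in neurons and 1, Dpysl4, in NPCs (median 1.02, camera adjusted p = 9.2e-14, and adjusted p = 0.165 with an estimated correlation). Crmp1 had a log2 change of 2.38 ± 0.06. Tuba1a went from 6646 to 24776 CPM, a value that is uncertain because tubulin genes share sequence.

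Markers of cortical layers were mostly higher in neurons. Of 14 deep-layer markers, 11 were higher in neurons (median 1.44, camera adjusted p = 6.6e-10, and adjusted p = 0.22 with an estimated correlation). Ldb2 and Sox5 had log2 changes of 2.71 ± 0.07 and 1.96 ± 0.06. Of 14 upper-layer markers, 9 were higher in neurons and 3 in NPCs (Pvrl3, Plxnd1 and Mdga1; median 0.68, camera adjusted p = 2.2e-04, and adjusted p = 0.22 with an estimated correlation). Inhba had a log2 change of 3.71 ± 0.15. Pou3f2 had a log2 change of 0.18 ± 0.05, which was lost with upper-quartile factors (0.08) and without either NPC replicate, and which turned to -0.03 with library size only. The difference between both layer lists was not tested. Of 7 markers of Cajal-Retzius cells, early neurons of the cortical surface, 5 were higher in neurons (6 adjusted over the list alone; median 1.94, camera adjusted p = 9.7e-04, and adjusted p = 0.26 with an estimated correlation). Reln went from 37.6 ± 0.21 to 144 CPM and Nhlh2 had a log2 change of 1.79 ± 0.08. Interneuron markers went both ways, with 7 of 19 higher in neurons and 7 in NPCs (8 adjusted over the list alone; camera adjusted p = 0.85). Calb2 went from 1.42 to 8.63 CPM.

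Markers of other cell types were measured beside these groups. All 7 markers of oligodendrocyte precursors were higher in NPCs, with a median of -5.89 (camera adjusted p = 2.7e-14, and adjusted p = 0.107 with an estimated correlation). All 15 endothelial markers were higher in NPCs (camera adjusted p = 5.1e-22, and adjusted p = 0.107 with an estimated correlation). Cldn5 was at 46.7 ± 1.19 CPM in NPCs and 1.12 CPM in neurons, and the glucose transporter gene Slc2a1 at 117 and 30.3 CPM. Of 9 markers of mural cells, which wrap blood vessels, 8 were higher in NPCs (median -4.54, camera adjusted p = 2.2e-14, and adjusted p = 0.107 with an estimated correlation). Vtn, Abcc9 and Rgs5 were at 63.0, 38.6 and 41.9 CPM in NPCs and below 2 CPM in neurons. Of 11 meningeal fibroblast markers, 10 were higher in NPCs (median -3.71, camera adjusted p = 1.2e-05, and adjusted p = 0.107 with an estimated correlation), among them Col3a1 and Igf2 at 20.4 and 16.3 CPM in NPCs. All 11 erythroid markers were higher in NPCs (median -2.59, camera adjusted p = 1.6e-09, and adjusted p = 0.107 with an estimated correlation). Hba-a2 was at 682 ± 128 CPM in NPCs and 94.7 CPM in neurons, and Hbb-b1 and Hbb-b2 had equal log2 changes of -2.59. These globin values are uncertain, because the copies hold nearly the same counts. All 13 microglia markers were higher in NPCs, with a median of -1.16, but the list did not pass (camera adjusted p = 0.087), though it did with limma-voom, no low-count filter, fry and camera on ranks (adjusted p from 0.0013 to 0.0049). Csf1r was at 9.21 and 4.11 CPM and C1qb at 7.14 and 3.70 CPM. Of 3 choroid plexus markers, 2 were higher in NPCs (Aqp1 and Otx2, camera adjusted p = 0.76, and 0.0011 with fry), and each was below 1 CPM in both groups. The Aqp1 call was lost without NPC replicate 1 or neuron replicate 1 and with DESeq2.

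Subunits of the BAF chromatin remodelling complex, which exchanges members when progenitors become neurons, moved in opposite directions. The 4 neuronal subunits were higher in neurons (median 1.84, camera adjusted p = 1.2e-05, and adjusted p = 0.22 with an estimated correlation). Actl6b went from 20.1 ± 1.39 to 131 CPM and Ss18l1 had a log2 change of 1.68 ± 0.06. The 4 progenitor subunits were higher in NPCs, with a median of -0.49, but that list did not pass (camera adjusted p = 0.195), though it did with limma-voom, no low-count filter, fry and camera on ranks (adjusted p from 0.013 to 0.035). Actl6a and Ss18 had log2 changes of -0.53 ± 0.06 and -0.75 ± 0.06. Of 10 genes of the REST repressor complex, which silences neuronal genes, 8 were higher in NPCs and 2, Hdac2 and Kdm1a, in neurons (median -0.86, camera adjusted p = 0.028, and adjusted p = 0.22 with an estimated correlation). Endothelial, mural and oligodendrocyte precursor markers were higher in the same NPC libraries (medians -4.44, -4.54 and -5.89). The histone deacetylase genes Hdac1 and Hdac2 moved in opposite directions, with log2 changes of -1.01 ± 0.06 and 0.41 ± 0.06, and Ctdsp2 fell with one of -0.92 ± 0.06.

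Metabolic and stress genes gave mixed results. Of 16 glycolysis genes, 12 were higher in NPCs and 4 in neurons (Hk1, Pfkp, Pfkm and Slc16a1), with a median of -0.53 (camera adjusted p = 0.070). The list passed with library size only (adjusted p = 0.029), upper-quartile factors (0.045), limma-voom (0.014), no low-count filter (0.011), without neuron replicate 1 (0.048) or neuron replicate 2 (0.011), and with fry (0.0021) and camera on ranks (0.016). Endothelial, mural and oligodendrocyte precursor markers were higher in these NPC libraries too (medians -4.44, -4.54 and -5.89). Eno1, Hk2 and Pkm2 had log2 changes of -0.83 ± 0.06, -1.41 ± 0.09 and -0.65 ± 0.06. Of 20 genes of cholesterol synthesis, 7 were higher in neurons and 6 in NPCs (camera adjusted p = 0.85). Fdft1 rose with a log2 change of 1.01 ± 0.05 and Idi1 fell with one of -0.89 ± 0.05. Of 17 apoptosis genes, 7 were higher in neurons and 6 in NPCs (camera adjusted p = 0.57, and 0.011 with fry). Bbc3, which promotes cell death, had a log2 change of 1.41 ± 0.12, and Trp53 one of -0.33 ± 0.06. Of 20 genes that respond to tissue dissociation, 5 were higher in neurons and 7 in NPCs (camera adjusted p = 0.55, and 0.0019 with fry). The immediate early genes Jun and Egr1 were higher in NPCs, at 134 and 36.0 CPM for Jun and 6.37 and 0.158 CPM for Egr1. Hspa8, a heat shock gene, had a log2 change of 0.26 ± 0.06 that was lost without NPC replicate 2 and with library size only.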

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

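Tests against a minimum change, counts divided by 2 and the comparison without genes at least 8-fold higher in NPCs were chosen after seeing the data. Counts of genes past an adjusted p of 0.05 stayed within 1.5 times of 11108 under the alternatives run, except with glmTreat against 1.5-fold, where 5387 genes passed, 2268 higher in neurons and 3119 in NPCs, because the test asks for a larger change. Genes changed at least 2-fold moved from 4578 to 2599 (1099 higher in neurons and 1500 in NPCs) with a filter of 5 CPM, which tested 11371 genes. With camera and an estimated correlation 0 lists passed, against 24, with 33 by fry and 27 on ranks. The estimate rests on 2 residual degrees of freedom. Leaving out each library in turn gave 9773 to 11252 genes, 4473 to 4597 genes at 2-fold, and 24 to 25 lists. DESeq2 called 10045 genes, of which 9966 were shared with the same sign, and limma-voom called 11110. Counts divided by 2 gave 10865 genes, and leaving out genes at least 8-fold higher in NPCs gave 10525. Library size as the only scaling called 11450 genes and moved the higher-in-neurons share of 2-fold genes from 38.2% to 29.3%, and upper-quartile factors moved it to 33.6%. With library size only, Sf3b1 turned to -0.17, Pou3f2 to -0.028, Ptbp2 to -0.061, Hnrnpk to -0.11 and Rbfox3 to -0.069, and the list medians of nonsense-mediated decay to -0.20, apoptosis to -0.15, cholesterol synthesis to -0.13 and interneurons to -0.025, changes of the size of the shift in the median of all genes. With upper-quartile factors Sf3b1 turned to -0.060, and the medians of these first 3 lists to -0.098, -0.049 and -0.023. With the filter of 5 CPM the median of nonsense-mediated decay turned to -0.034 and that of cell cycle inhibitors to 0.018. Leaving out each library gave nonsense-mediated decay medians of -0.052 to 0.064, SR factor medians of -0.084 to 0.00082 and Ttr changes of -0.48 to 0.31. Of the values of named genes under alternatives, 1527 kept their direction and side of the threshold, 17 lost it, 12 gained it and 8 turned. Of list medians, 490 kept both, 26 lost the threshold, 25 gained it and 12 turned. The labels do not say whether libraries with the same duplicate number share a litter or a sort. Deviations of same-numbered libraries correlated at 0.0186, which cannot settle this. The replicate block gave 11206 genes, 4564 at 2-fold and 24 lists, and among named genes Syt11 no longer passed while Eif4a3 and Rbfox3 did. With 52611828 to 55615142 counts per library, 2096 genes were called that were higher in one group by under 25%, and recovery of changes that small was not simulated.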

Other observations

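The tests of cells inside the progenitor gate, of a lower share of neural cells, of a fixed share of neurons, of intermediate progenitors and of the shift of long loci between duplicates, and the gene families, were chosen after the results were seen. Some gene families share members with the fixed lists, as 13 of 35 kinesin genes, 9 of 76 potassium channel genes and 3 of 46 collagen and laminin genes did, so they are not independent of them. Of 62 histone genes of the replication clusters, 54 were higher in NPCs and 5 in neurons, with a median log2 change of -1.46 (camera adjusted p = 5.7e-06, and adjusted p = 0.44 with an estimated correlation). Hist1h2ac went from 192 CPM in NPCs to 43.9 CPM in neurons, though histone copies share sequence and their single values are uncertain. Of 46 collagen and laminin genes, 40 were higher in NPCs, with a median of -2.44 (camera adjusted p = 8.3e-12, and adjusted p = 0.37 with an estimated correlation), and the basement membrane gene Col4a1 went from 140.3 to 6.03 CPM. Markers of endothelial, mural and meningeal cells, which express such genes, were higher in the same NPC libraries (medians -4.44, -4.54 and -3.71). Of 26 genes whose symbol begins as an integrin's, 18 were higher in NPCs (median -1.20, camera adjusted p = 0.0021, and adjusted p = 0.41 with an estimated correlation). These families had the same direction with each of the 4 scalings run.

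Protocadherin genes, which encode adhesion proteins of the neuronal surface, were higher in neurons for 63 of 70 genes and in NPCs for 7, but many of these rows repeat a shared signal, because genes of a cluster share their last exons. The 14 alpha-cluster rows had log2 changes from 1.66 to 1.73, and the 22 gamma-cluster rows lay at 186 to 199 CPM in NPCs and 297 to 319 CPM in neurons. Of the 34 rows not assigned to these clusters by their symbols, 27 were higher in neurons and 7 in NPCs, and Pcdh9 went from 109 to 358 CPM. Kinesin genes went both ways, with 12 of 35 higher in neurons and 18 in NPCs (camera adjusted p = 0.0064, and adjusted p = 0.41 with an estimated correlation). Kif11, a mitotic motor gene, had a log2 change of -2.05, and Kif5a, an axonal transport motor gene, one of 1.95. Zinc finger protein genes were higher in neurons for 194 of 347 and in NPCs for 71 (camera adjusted p = 0.017, and adjusted p = 0.41 with an estimated correlation), and with library size only for 127 against 105. Genes of the nuclear-encoded respiratory chain were higher in neurons for 35 of 72 and in NPCs for 6, which became 8 and 27 with library size only. Ribosomal protein genes were higher in NPCs for 32 of 81, and for 71 with library size only. Potassium channel genes were higher in neurons for 43 of 76 (camera adjusted p = 0.053). The ribosomal and respiratory chain families did not pass (camera adjusted p = 0.51 and 0.27), nor did those of the proteasome, tRNA synthetases, small nucleolar RNA hosts and microRNAs (camera adjusted p = 0.78 to 0.94).

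Vascular, mural, meningeal, blood and microglial markers were higher in NPC libraries for 57 of 59 tested genes (96.6%), a share that restates the pattern and does not test whether cells of those types were inside the progenitor gate. Of these genes, 0 are in another fixed list, and 6 were at 5 CPM or more in neurons against 37 in NPCs. The choice among the 3 scalings compared was argued against as the source for endothelial markers. Their median moved by 0.21, from -4.44 to -4.65, while the median of all genes moved from -0.02 to -0.23. The microglia median, the smallest in size of these lists, ran from -1.16 to -1.37. Whether a lower share of neural cells raised every other type alike could not be decided. The medians compared were known when the test was chosen, and each is a ratio to the neuron libraries. The values show only that the ratio was not equal for both lists. Microglia and endothelial medians lay 3.28 apart on the log2 scale (permutation test of 100000 draws, two-sided p = 7e-05). Genes were permuted between the lists, so this p measures spread between genes, which are not independent replicates, and not between libraries. Microglia markers were also low, summing to 42.4 CPM in NPCs and 20.2 CPM in neurons, which limits this comparison further. Cells of vessels and meninges in a gate that takes GFP without mRFP remain a candidate source, as does expression of these genes by progenitors, which was not tested.

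Neuronal transcripts were present in NPC libraries, where Dcx was at 34.3% of its neuron level and pan-neuronal markers had a median of 28.1%. One fixed share of neurons like the sorted ones would leave few genes below the Dcx ratio. Of 99 members of 5 neuronal lists at 20 CPM or more in neurons, 44 (44.4%) lay below it by more than 2 standard errors, which neither reaches the 50% that would exclude it nor stays within what it needs. The share was 60% for pan-neuronal markers, 60.9% for ion channels and 8.33% for upper-layer markers, so the outcome depends on which lists are taken, and a fixed share cannot be told apart from the alternatives by this test. Intermediate progenitors and newborn cells inside the gate also remain open, since the 86.7% of intermediate progenitor markers higher in NPCs repeats the result of that list, and markers of newborn cells were not analysed here.

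Genes with long loci were looked at because long genes are often neuronal. Spearman's rho of log2 change with locus length was 0.06 across 14826 genes, which are not independent replicates, and the median log2 change of the 1483 genes with the longest loci was 0.26. The trend was too weak to test 2 sources: the longest loci exceeded the shortest by more than 0.2 in 1 of 5 bins of transcript length, but by only 0.15 before binning, and rho was 0.047 without the genes of the fixed lists, a small drop. A difference between libraries of one group was argued against, because the median of the 1483 genes with the longest loci lay 0.28 above that of all genes between groups (0.22 to 0.37 in 2000 gene bootstraps) and at most 0.029 from it between duplicates. The source of the trend is left open, and no biological reading of it is offered.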
